A study of Arabidopsis thaliana with 4 samples.

How the data were processed

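Total RNA of whole seedlings, 10 µg per sample, was made into biotin-labelled cRNA by a standard Affymetrix protocol and hybridised to 1 array per group, per the labels' protocols. The deposited table holds 22810 probe sets for 4 samples on a linear scale, and its unit is intensity, the brightness of a probe set summarised by the authors with MAS5, per the submitters' processing notes; the version and settings of MAS5 are not given in the sources used here. From the values, the mean without the top and bottom 2% of probe sets was the same on every array to within rounding, so the arrays had been scaled to one target before deposit. MAS5 subtracts a mismatch signal probe by probe, which makes ratios of dim probe sets noisy. No detection calls were used here.

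Sample columns were assigned to WT, transWT, emf2 and rescued emf2 from the sample labels. The 64 control probe sets were left out of all counts and of the floor, and were used to compare arrays. They did enter the trimmed mean for scaling, and the quantile and cyclic loess alternatives. Each array was rescaled to the same 2%-trimmed mean, signals were floored at the 40th percentile of the 22746 other probe sets over all 4 arrays (87.6), and log2 ratios were taken between single arrays. A probe set was counted as higher or lower where the ratio was at least 2-fold with the brighter array above the floor; one below the floor on both arrays was not tested. A ratio with the dimmer array below the floor is a bound, the brighter signal over the floor, and is written as at least N-fold. With 1 array per group no single comparison has a test. An additive fit of background and transgene over the 4 arrays leaves 1 residual degree of freedom and was run with limma (lmFit and eBayes, Benjamini-Hochberg adjustment) after the data were seen, on probe sets above the floor on all arrays; it assumes that each effect is the same in both pairs. On simulated data of 12145 probe sets with an SD of 0.25 it called 60% of true 2-fold and 100% of 3-fold differences of background, and 6 unchanged probe sets. That simulation gave every probe set the same SD and each background difference its full size in both pairs, so its shares do not carry over to the real arrays. No array has a depth in counts.

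The 5 comparisons, the floor, the threshold, 17 gene lists with 279 members, the rule for named genes and the alternatives were set before the data were examined. Named genes are, for each comparison, the 8 highest and 8 lowest log2 ratios among genes above the floor on both arrays, the 4 highest and 4 lowest bounds, up to 4 members of each list past 2-fold with the largest change, and EMF2, FLC, FT, AG, AP3, PI, SEP3 and the Polycomb list where a probe set names them. Where a list had no member past 2-fold, up to 2 members could be given with values. Other genes named were chosen after their values were seen, as the text says at each.

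Probe sets were named through the platform's annotation table, which lists 14016 of the 22810: 13513 with 1 gene and 503 with several. Another 8794 are not listed and stay unnamed here, which does not mean that they lack a gene. Of the 13513, 13436 were matched through the gene ID to current names (assembly TAIR10.1, used for names only). No coordinates are given. A gene with several probe sets is represented by the one with the highest mean signal, and no probe set with several genes was named. Of the 279 list members 43 had a named probe set, so a list stands for these members alone.

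For each list with at least 3 measured members in a comparison, the median log2 ratio was set among 10000 random lists of the same size drawn from the named genes in 20 bins of mean signal. In both, members below the floor on both arrays enter with a log2 ratio of 0; where a list holds such members, the median of its measured members is given too. A bound enters a median at its value, which understates the ratio of that member. The percentile describes these arrays and is no p-value. This minimum on measured members was set after seeing that some lists lay below the floor. Plastid-encoded genes, 69 in all, were grouped after their values were seen and set against nuclear genes. The share of probe sets keeping a 2-fold difference was taken between pairs with no array in common, with an exact (Clopper-Pearson) 95% interval that covers counting over probe sets only, and beside it the share expected from probe sets matched on mean signal. The matched share is that of all probe sets in the same bins of mean signal, the selected ones included. Measurement error was estimated from 43 genes with more than 1 probe set above the floor on every array, as the SD of the difference of the log2 ratios of the brightest pair divided by the square root of 2.

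The alternatives were the values as deposited, quantile normalization, scaling to the median, cyclic loess, floors at the 25th and 60th percentile, no floor with a pseudocount of 1, probe sets above the floor on both arrays, thresholds of 1.5-fold and 3-fold, genes in place of probe sets, another comparison pair for the kept share, and the mean of all probe sets of a gene. Those for the plastid median, and list medians over measured members only, were added after seeing the data, as was the additive fit. The steps were tested on simulated data: arrays made from the real mean signals of 22746 probe sets with an SD of 0.25 per array on the log2 scale and 200 changed probe sets gave, for emf2 over WT, 42.0% of true 2-fold, 92.0% of 3-fold, 96.0% of 4-fold and 100% of 8-fold changes at the 2-fold threshold, and 58 of 22546 unchanged probe sets. The changed probe sets were all drawn from those with a mean signal more than 2-fold above the floor. Every probe set had the same SD, and the unchanged ones included those near or below the floor. These shares and the number of unchanged probe sets called therefore do not carry over to the real arrays. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for cyclic loess.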

Results

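RNA of whole Arabidopsis seedlings was compared between the Columbia wild type (WT), the embryonic flower mutant emf2, and each of these carrying 35S::BoEMF2.1, named transWT and rescued emf2. EMF2 is a subunit of Polycomb repressive complex 2, which holds floral genes silent during vegetative growth, and BoEMF2.1 is a Brassica oleracea gene named after it, here under a strong constitutive promoter. Seedlings were 7 days old and had grown in short days of 8 h light and 16 h dark at 21 °C. The transgenic seedlings grew on plates with hygromycin and the other two groups on plates without it, so transgene and hygromycin always went together. Each of the 4 groups was measured once, on 1 Affymetrix array of 22810 probe sets. There are no replicates: no difference between a pair of arrays has a replicate check or a p-value, and the number of arrays limits the precision.

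Of the 22746 probe sets that are not controls, 14015 were above the floor (a signal of 87.6) on the WT array, 13782 on the transWT array, 13399 on the emf2 array and 13394 on the rescued emf2 array. The brightest probe set reached 23754.5 in WT and 24807.4 in emf2, against 35034.9 in transWT and 35620.7 in rescued emf2. Probe sets for bacterial and phage control RNAs also separated the arrays in these pairs. Relative to WT, the median of 18 hybridization control probe sets was 1.03-fold in emf2, 1.21-fold in transWT and 1.35-fold in rescued emf2. For 7 probe sets of bacterial poly-A control RNAs the median was 1.05-fold in emf2, 1.92-fold in transWT and 2.48-fold in rescued emf2. The ratio of 5′ to 3′ signal was 0.52 in WT, 0.40 in transWT, 0.43 in emf2 and 0.39 in rescued emf2 for actin, and 0.92, 1.02, 1.1 and 0.95 for GAPDH. For 43 genes with more than 1 probe set above the floor on all arrays, the error of a log2 ratio estimated from the disagreement of their probe sets was between 0.27 and 0.38 (SD), depending on the comparison; it holds no variation between plantings.

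**Figure D1:**
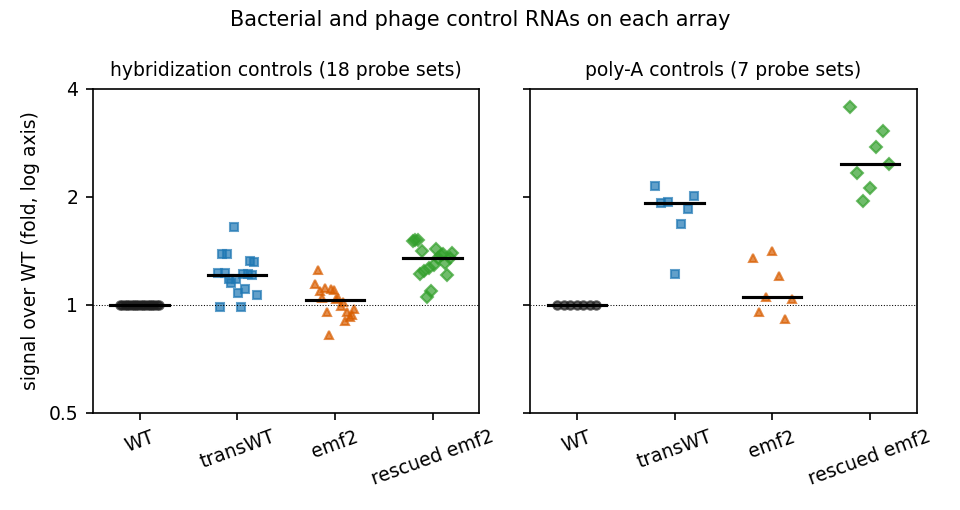
Signal of control RNA probe sets on each of the 4 arrays relative to the WT array (fold, log axis); points are probe sets and black bars are medians. The poly-A control medians lie at 1.92 and 2.48 on the transWT and rescued emf2 arrays and at 1.05 on the emf2 array.

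EMF2 itself, FLC, FT, AG, AP3, PI and SEP3 have no probe set that is named here, so the genotype of the arrays was not checked by EMF2 signal and these targets were not analysed here. The same holds for all 15 genes of the floral organ identity list. Of the flowering-time list, 4 of 21 genes were named. AGL42 had signals of 9.70 in WT, 3.30 in transWT, 129 in emf2 and 98.7 in rescued emf2, and AGL24, FD and AGL19 were below the floor on every array. Within the carpel and ovule list SPT, a regulator of carpel growth, read 147 in WT, 90.3 in transWT, 206 in emf2 and 170 in rescued emf2, within 2-fold in every comparison, and INO and SPL were below the floor. In rescued emf2 over transWT SPT passed 2-fold after quantile normalization (log2 1.06) and cyclic loess (1.03). All named members of the lists for Polycomb proteins (BMI1C), shoot meristem (CLV3), anther and pollen (A9 and AMS), seed maturation (PAP85) and defense (PDF1.2A and PDF1.2B) were below the floor on all 4 arrays.

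The effect of the emf2 mutation without the transgene was read from emf2 over WT. Plastid-encoded transcripts were lower in emf2 as a group, and the root hair expansins EXPA18 and EXPA7 were higher. EXPA8, an expansin that loosens cell walls, was at least 49.8-fold lower, and MSRB6, a methionine sulfoxide reductase, was 30.8-fold lower (3214 in WT and 104 in emf2). AT3G05730, a defensin-like gene, was 34.6-fold lower and AT5G11420, a cell wall protein gene of the DUF642 family, 30.5-fold lower. TET9, a tetraspanin, was at least 24.4-fold higher.

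Other transcripts with much lower signal in emf2 were AT2G29290, a short-chain dehydrogenase gene (13.9-fold), AT1G22690, of the gibberellin-regulated GASA family (12.5-fold), AT5G62360, of the pectin methylesterase inhibitor family (11.9-fold), and AT4G12980 (9.67-fold). AT3G16670, AT5G50335 and AT5G63180, a pectate lyase gene, were below the floor in emf2 and at least 36.6-fold, 24.6-fold and 21.0-fold lower than in WT. On the other side, AT4G22610, of the lipid-transfer protein family, was 12.9-fold higher, and AT4G12490, of the same family, 8.72-fold higher. AT2G19970 and AT4G30320, both PR-1-like genes, were 9.46-fold and 8.69-fold higher. AT5G38020, a methyltransferase gene, was 9.90-fold higher, AT5G47330 9.50-fold, AT1G22890 9.37-fold and COR27, a cold- and clock-regulated gene, 8.30-fold. BGLU45, a beta-glucosidase linked to lignin precursors, was at least 12.0-fold higher, AT5G05220 at least 10.9-fold, and AT3G02480, of the late embryogenesis abundant family, at least 10.8-fold.

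Plastid-encoded genes were grouped after their values had been seen. Of 69 such genes, 64 were measured in this comparison; 47 were at least 2-fold lower in emf2 and 0 were at least 2-fold higher. The median log2 ratio was -1.78 over the measured genes and -1.64 over all 69, with genes below the floor on both arrays at 0. The latter lay below the medians of all 10000 random lists of nuclear genes matched on signal, the lowest of which was -0.34. By function, all 6 ATP synthase genes were at least 2-fold lower (median log2 of measured genes -1.68), as were 11 of 14 ribosomal protein genes (-2.07), 7 of 9 NDH complex genes (-1.64), 11 of 19 photosystem genes (-1.31), 3 of 4 RNA polymerase genes (-1.81) and 2 of 4 cytochrome b6f genes (-1.0). Among them rpl16 was 14.4-fold lower, psbB 8.05-fold, psaA 7.86-fold and rbcL, the large subunit of Rubisco, 3.91-fold. Of the other 17 measured genes, rpoB (at least 1.67-fold lower) and petN (at least 1.08-fold lower) have only bounds. The rest lay within 2-fold, from ndhI (log2 ratio -0.97) to psbM (0.04), with psbF at -0.25, rpl33 at -0.41 and petB at -0.42 among them.

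Of the nuclear photosynthesis list 7 of 39 genes were named and measured. PSBY, a photosystem II subunit, was 2.01-fold lower in emf2 and the other 6 lay within 2-fold, with a list median log2 of -0.39 (percentile 5.75 of random lists). With each array scaled to its median, PSBY lay within 2-fold too (-0.96). In the root marker list EXPA18 and EXPA7, expansins of root hairs, were 4.19-fold and 2.67-fold higher in emf2, while PYK10, a root beta-glucosidase, was at 1.06-fold; the list median was 1.42 (percentile 99.8). Cold-list genes went both ways: COR15A was 2.88-fold higher, COR15B 3.03-fold lower, and COR47 within 2-fold (log2 0.22); their median of 0.22 stood at percentile 70.7. MCM7, a DNA replication helicase subunit, was 2.91-fold lower, while AUR1 and AUR2 of the same cell division list lay within 2-fold (list median -0.10, percentile 50.8). IAA29, an early auxin-response gene and the only named gene of its list, was at least 2.70-fold lower. GI of the clock list was at a log2 ratio of -0.67, and the measured detoxification genes UGT73B5 (0.89) and GSTU25 (0.17) lay within 2-fold. UGT73B5 passed 2-fold after quantile normalization (1.03) and, barely, after cyclic loess. No flavonoid gene was above the floor on either array. The 4 reference genes GAPC2, TIP41, SAND and UBC21 lay within 2-fold here and in the 4 other comparisons.

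Several developmental regulators outside the lists were singled out after their values were seen. ALC, a bHLH gene of fruit opening, was at least 5.27-fold higher in emf2, and ULT1, a SAND-domain regulator of floral meristem size, 2.86-fold higher. YAB5, of the YABBY family of leaf polarity genes, was at least 7.41-fold lower, STOMAGEN, a peptide that raises stomatal density, 4.18-fold lower, SMZ, an AP2-like repressor of flowering, 2.82-fold lower, and its relative SNZ at least 2.25-fold lower. The Calvin cycle genes PRK and SBPASE were 2.61-fold and 3.13-fold lower. In all, 1076 probe sets were at least 2-fold higher and 1633 at least 2-fold lower in emf2, 18.5% of the 14653 tested, and 175 and 291 of them at least 4-fold. These are differences between 2 arrays, so variation between plantings is part of each.

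**Figure D2:**
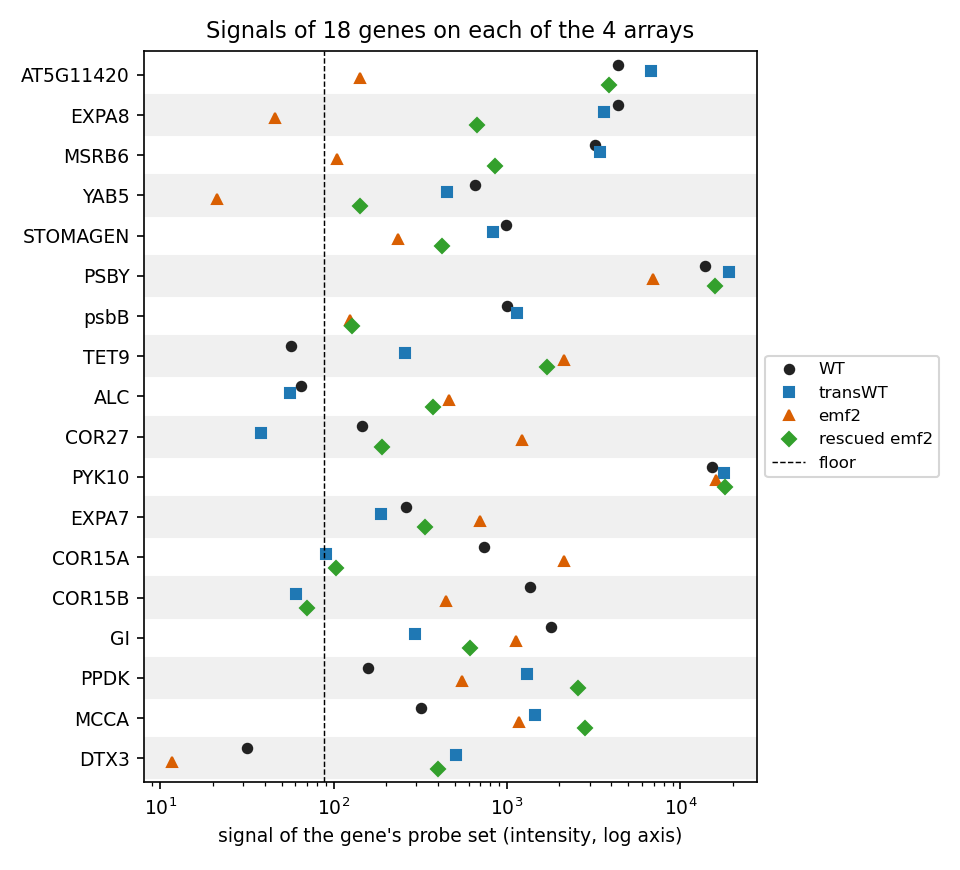
Signal of 18 named genes (linear intensity on a log axis) on each of the 4 arrays; each marker is 1 array and the dashed line is the floor at 87.6. EXPA8 and MSRB6 are lowest on the emf2 array, and COR15A and COR15B are low on both transgenic arrays.

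The effect of 35S::BoEMF2.1, with hygromycin, in the wild type was read from transWT over WT. All measured genes of the cold list were lower in transWT. COR15A, which encodes a chloroplast protein made in the cold, was 8.13-fold lower and its paralog COR15B at least 15.5-fold lower. GI, a clock gene that promotes flowering, was 6.12-fold lower. PPDK, pyruvate orthophosphate dikinase, was 8.27-fold higher, and CP1, a cysteine protease, 14.0-fold higher.

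AT1G65490 was 15.9-fold higher in transWT, AT1G64500, of the glutaredoxin family, 8.92-fold, AT1G68440 8.87-fold, AT1G29090, a papain-like protease gene, 8.81-fold, AT1G43910 8.40-fold and AT3G50560 8.32-fold. DTX3, a MATE efflux transporter and member of the detoxification list, was below the floor in WT and at least 5.78-fold higher in transWT; AT1G26390, AT1G50040 and AT1G14550, a peroxidase gene, were at least 6.29-fold, 6.13-fold and 5.97-fold higher. Among the lower transcripts were AT4G16146 (13.0-fold), AT1G20030, of the thaumatin family (12.3-fold), AT4G30650, of the low-temperature-responsive RCI2 family (12.2-fold), AT1G56300, a DnaJ-domain gene (12.1-fold), AT5G62360 (10.8-fold), AT1G12845 (8.72-fold) and BGLU44 (8.68-fold). AT1G11210 was at least 13.4-fold lower, AT2G39920 at least 9.82-fold and AT5G44440, of the berberine bridge enzyme family, at least 7.73-fold.

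All 3 measured genes of the cold list were at least 2-fold lower, with COR47 at 2.28-fold, and the median log2 of -3.02 was reached by 1 of 10000 random lists; it was -1.51 with the floor at the 60th percentile. In the flavonoid list DFR, which makes anthocyanin precursors, was at least 3.54-fold higher, UF3GT at least 1.60-fold and UGT75C1 at least 1.31-fold, all 3 below the floor in WT. With these bounds at their values the median was 0.68, and 0.53 (percentile 100) with 5MAT, below the floor on both arrays, at 0. It was 0.30 after cyclic loess, 1.79 with the floor at the 25th percentile and 0 at the 60th. LHCB4.3, a light-harvesting gene, was 4.73-fold higher and the other 6 photosynthesis genes lay within 2-fold (list median 0.46, percentile 97.5; 0.12 after quantile normalization and 0.22 after cyclic loess). GSTU25 (0.41) and UGT73B5 (0.45) of the detoxification list lay within 2-fold (list median 0.45, percentile 93.3). Root markers lay within 2-fold (median -0.42, percentile 10.9; -0.018 with the floor at the 60th percentile), and of the cell division list MCM7 was 2.69-fold lower and the others within 2-fold (median -0.12, percentile 50.9). Of 66 measured plastid-encoded genes, 11 were at least 2-fold higher and 4 lower, with a median of 0.23, and of 0.21 over all 69 (percentile 99.97; 0.11 after quantile normalization). Among the higher were petL (2.73-fold) and rps4 (2.66-fold), and the 4 lower were rpl36 (5.81-fold), rpl14 (3.58-fold), rpoA (2.34-fold) and rpl22 (2.14-fold). PORB, of chlorophyll synthesis and singled out after its value was seen, was 4.86-fold lower.

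In this comparison 567 probe sets were at least 2-fold higher and 778 at least 2-fold lower, 9.20% of 14620 tested. The split depends on the scaling: it was 700 higher and 615 lower with each array scaled to its median and 672 and 613 after cyclic loess. Hybridization and poly-A control probe sets were 1.21-fold and 1.92-fold brighter on the transWT array, and the transgene, hygromycin and array cannot be told apart here.

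The same transgene in the mutant was read from rescued emf2 over emf2. AT5G11420, 30.5-fold lower in emf2 than in WT, was 27.3-fold higher in rescued emf2 than in emf2, with a signal of 3875 against 4335 in WT. Both ratios hold the same emf2 array, so an odd reading there alone could give such a reversal. EXPA8 was at least 7.64-fold higher than in emf2, though at 669 it was still 6.52-fold below WT. Among plastid transcripts, petL was higher by 11.4-fold, rpl16 by 9.47-fold and psbC by 8.29-fold. COR15A was 20.7-fold lower.

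CP1 was 12.1-fold higher in rescued emf2 than in emf2, AT2G34930, a leucine-rich repeat gene, 9.45-fold, AT3G50560 9.12-fold and SWEET2, a sugar transporter gene, 8.61-fold. AT1G56060, AT1G66100, a thionin gene, and AT1G64500 were at least 10.1-fold, 9.39-fold and 7.52-fold higher. Lower transcripts were the lipid-transfer family gene AT4G12500 (14.0-fold), AT1G24575 (9.95-fold), AT4G30650 (8.14-fold), AT1G75880, a GDSL lipase gene (8.06-fold), AT1G76960 (7.99-fold), AT5G47330 (7.28-fold) and AT2G43535, a defensin-like gene (7.04-fold). AT3G28500, AT1G10770, AT2G23910 and AT1G30760 were at least 7.69-fold, 6.09-fold, 5.55-fold and 5.39-fold lower. HIS1-3, a histone H1 variant and singled out after its values were seen, was at least 6.44-fold higher in emf2 than in WT and 4.71-fold lower in rescued emf2 than in emf2. These ratios too share the emf2 array.

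Of the photosynthesis list 4 of 7 genes were at least 2-fold higher in rescued emf2: LHCB4.2 (2.42-fold), PSBY (2.29-fold), LHCB4.3 (2.12-fold) and RCA, the Rubisco activase (2.0-fold). The list median log2 was 1.0 (percentile 99.9), against 0.58 after quantile normalization and 0.70 after cyclic loess. RCA lay within 2-fold after quantile normalization (0.58) and cyclic loess (0.70), and after cyclic loess PSBY (0.94) and LHCB4.2 (0.997) did too. Of 60 measured plastid-encoded genes, 29 were at least 2-fold higher and 1, rpl36, was 3.34-fold lower, with a median of 0.88, and of 0.58 over all 69, above all random lists (0.18 with the floor at the 60th percentile). All 5 measured ATP synthase genes were among the higher (median 2.09), against 6 of 18 photosystem genes (0.08). In the cold list COR15A and COR15B (at least 5.10-fold) were lower and COR47 within 2-fold (list median -2.35, below all random lists; -0.79 with the floor at the 60th percentile). EXPA18 and EXPA7 of the root markers were 2.96-fold and 2.09-fold lower and PYK10 within 2-fold (median -1.07, percentile 0.34); EXPA7 was at -0.98 after quantile normalization and -0.97 after cyclic loess. DTX3 was at least 4.56-fold higher, with GSTU25 (0.17) and UGT73B5 (-0.27) within 2-fold (detoxification median 0.17, percentile 76.1). GI (-0.88) and the 3 cell division genes (median 0.39, percentile 88.2) lay within 2-fold.

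Rescued emf2 had 826 probe sets at least 2-fold higher and 702 at least 2-fold lower than emf2, 10.8% of 14122 tested. Poly-A control probe sets were 2.38-fold brighter on the rescued emf2 array, which also differs from emf2 in hygromycin.

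What still differed from the wild type in the rescued mutant was read from rescued emf2 over WT. TET9 was at least 19.3-fold higher in rescued emf2, and AT1G65490, also higher in transWT, was 40.7-fold higher. PPDK was 16.3-fold higher, and MCCA, an enzyme subunit of leucine breakdown, 8.83-fold. AT3G16670 was at least 36.6-fold lower and COR15B at least 15.5-fold lower. The plastid ribosomal protein genes rpl36, rpl22 and rpl14 were 22.2-fold, 11.7-fold and 8.88-fold lower.

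Further transcripts were AT4G37220 (12.2-fold higher), AT2G41730 (11.2-fold), AT1G22890 (9.51-fold), AT1G72060 (8.83-fold) and AT1G43910 (8.77-fold), with AT4G28460, UGT76E12, a glycosyltransferase, and AT3G18250 at least 7.00-fold, 6.66-fold and 6.39-fold higher. AT2G43550, a defensin-like gene, was 15.9-fold lower, AT1G11210 13.0-fold, AT1G73600 9.86-fold, AT5G63180 9.79-fold and psbB 7.91-fold. AT5G45650, a subtilase gene, and AT5G44400, of the berberine bridge enzyme family, were at least 11.9-fold and 8.15-fold lower. Of 64 measured plastid-encoded genes 19 were at least 2-fold lower and 1, petL, was 3.29-fold higher, with a median of -0.64, and of -0.60 over all 69, below all random lists. In the cold list COR15A (7.18-fold) and COR15B were lower (median -2.84, below all random lists; -1.51 with the floor at the 60th percentile). GI was 2.93-fold lower, MCM7 4.54-fold lower (cell division median 0.34, percentile 87.5), IAA29 at least 2.70-fold lower, DTX3 at least 4.56-fold higher (detoxification median 0.62, percentile 94.5) and LHCB4.3 2.12-fold higher (photosynthesis median 0.45, percentile 89.7; 0.13 after quantile normalization and 0.11 after cyclic loess). The root markers lay within 2-fold (median 0.35, percentile 83.5).

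Rescued emf2 had 863 probe sets at least 2-fold higher and 1444 at least 2-fold lower than WT, 15.8% of 14593 tested. This split also depends on the scaling, with 1063 and 1093 after quantile normalization and 1047 and 1049 after cyclic loess.

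The mutant background was compared with the wild-type background, both with the transgene and hygromycin, in rescued emf2 over transWT, a pair of arrays separate from emf2 and WT. TET9 was 6.55-fold higher in rescued emf2 and AT4G22610 5.45-fold, both also higher in emf2 than in WT. EXPA8 was 5.39-fold lower, MSRB6 4.05-fold and psbB 9.03-fold. ALC was at least 4.26-fold higher, and AT3G16670 at least 10.6-fold lower.

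AT1G12010, an ACC oxidase gene of ethylene synthesis, was 7.08-fold higher, AT1G20030 4.69-fold, AT4G37220 4.35-fold, AT3G60520 4.32-fold, AT5G57655, a xylose isomerase gene, 4.26-fold and AT4G36010, of the thaumatin family, 4.15-fold. UGT76E12, AT1G16950 and AT5G60140 were at least 6.66-fold, 4.16-fold and 3.41-fold higher. Lower were AT5G63180 (5.76-fold), ndhH (5.75-fold), rpl22 (5.46-fold), rpoC2 (4.54-fold) and BZIP61 (3.98-fold), with psbT, BHLH101, a regulator of iron uptake, and AT5G45650 at least 6.01-fold, 4.90-fold and 4.72-fold lower. Of 66 measured plastid-encoded genes 26 were at least 2-fold lower and 0 higher, with a median of -0.76, and of -0.70 over all 69, below all random lists. Of the genes singled out in emf2 over WT, YAB5 was 3.15-fold lower and SMZ 2.21-fold lower, while ULT1 (log2 0.84), STOMAGEN (-0.98), PRK (-0.61) and SBPASE (-0.41) lay within 2-fold and SNZ was at least 1.21-fold lower. Of the flavonoid list DFR was 3.35-fold lower, UF3GT at least 1.60-fold and UGT75C1 at least 1.31-fold, with a median of -0.68 over these 3, bounds included, and -0.53 (percentile 0.04) with 5MAT at 0. That median was -0.30 after cyclic loess, -1.82 with the floor at the 25th percentile and 0 at the 60th. LHCB4.3 was 2.23-fold lower and the other 6 photosynthesis genes within 2-fold (median 0.00, percentile 32.8). GI was 2.09-fold higher. The 3 root markers lay within 2-fold with a median of 0.82 (percentile 99.5; 0.37 with the floor at the 60th percentile). The measured genes of the cold list (COR47 0.88 and COR15A 0.18), the detoxification list (median -0.06, percentile 42.0) and the cell division list (-0.28, percentile 23.4) lay within 2-fold, and IAA29 of the auxin list was at least 1.73-fold lower. In all 322 probe sets were at least 2-fold higher and 426 at least 2-fold lower, 5.25% of 14250 tested.

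How much of the mutant difference was kept with the transgene was read across these separate pairs of arrays. Of the 1076 probe sets at least 2-fold higher in emf2 than in WT, among them TET9, ALC and AT4G22610, 205 were at least 2-fold higher in rescued emf2 than in transWT, or 19.1% (exact 95% binomial interval 16.7 to 21.5, counting over probe sets only). All probe sets matched on mean signal, with the selected ones included, gave 2.39%. Of the 1633 lower, among them EXPA8, MSRB6 and psbB, 287 were lower again, or 17.6% (15.8 to 19.5), against 3.35% of matched probe sets. The median log2 ratio of the higher set was 1.38 in emf2 over WT and 0.51 in rescued emf2 over transWT, and that of the lower set -1.39 and -0.57. Part of that gap comes from selecting probe sets on the first pair.

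Across 15111 probe sets above the floor on at least 1 array, the log2 ratios of the separate pairs correlated with Pearson's r of 0.64 and Spearman's rho of 0.61 for the mutant effect, with a slope of 0.38 and SDs of 0.83 without and 0.49 with the transgene. For the transgene effect, transWT over WT against rescued emf2 over emf2, r was 0.49 and rho 0.44. These are correlations across genes of single arrays, and genes are not independent replicates. Of the 567 probe sets at least 2-fold higher in transWT than in WT, CP1, DTX3 and AT3G50560 among them, 271 (47.8%) were at least 2-fold higher in rescued emf2 than in emf2, against 6.33% of matched probe sets. Of the 778 lower, COR15A, COR15B and AT4G30650 among them, 193 (24.8%) were lower again, against 5.78%.

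An additive limma fit of background and transgene over the 4 arrays, added after the data were seen, has 1 residual degree of freedom and takes the difference between the pairs as its error. A background difference that is smaller with the transgene therefore counts partly as error, and a lack of calls does not show that such differences are absent. Over 12145 probe sets above the floor on all arrays, at a Benjamini-Hochberg adjusted p of 0.05, it called 0 probe sets for the emf2 background (1352 higher and 1702 lower at an unadjusted p of 0.05). For the transgene with hygromycin it called 6 higher and 1 lower (1153 and 1359 unadjusted). The higher ones with a name were CP1 (mean log2 ratio 3.70, limma adjusted p = 0.0345), AT3G50560 (3.12, adjusted p = 0.0345) and AT2G41250 (2.75, adjusted p = 0.0476). The lower one was AT4G30650 (-3.31, limma adjusted p = 0.0451). Each went the same way in both pairs. Such agreement is built into the call, since the error is the difference between the pairs, and is no further support.

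**Figure D3:**
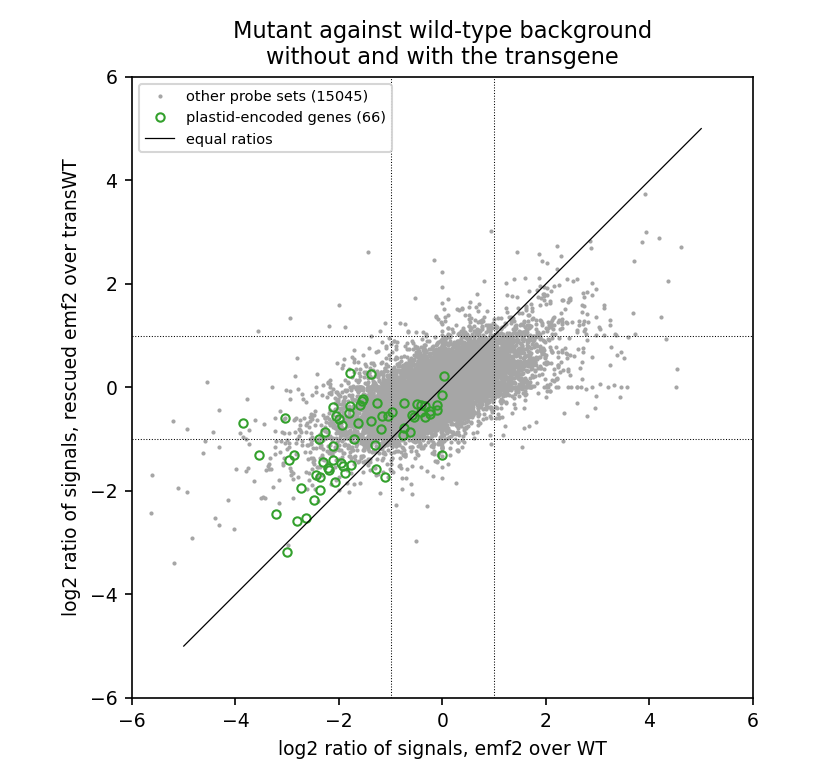
Log2 ratio of emf2 over WT (x axis) against rescued emf2 over transWT (y axis) for 15111 probe sets; each point is 1 probe set, dotted lines mark 2-fold, the solid line equal ratios, and green circles plastid-encoded genes. The points follow a slope of 0.38, and the plastid-encoded genes lie mostly at the lower left, with medians over all 69 of -1.64 and -0.70.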

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

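The tests of degraded RNA, a single-array artifact and bright signals were chosen only after the results they bear on had been seen. So was that of a hygromycin or array batch, while those of gain and measurement error were not. The harvest-hour test was drawn from genes already seen to be lower, and only the value of COR28 was unseen.

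Some probe sets drew attention because the mutant differed from the wild type in opposite directions without and with the transgene. Between emf2 over WT and rescued emf2 over transWT, 10 probe sets were at least 2-fold apart in opposite directions, against 205 and 287 higher or lower in both. AT5G62360, of the pectin methylesterase inhibitor family, was 11.9-fold lower in emf2 than in WT and had a log2 ratio of 1.095 in rescued emf2 over transWT. AT5G44440, of the berberine bridge enzyme family, was at least 7.73-fold lower in emf2 and at a log2 ratio of at least 1.34 in rescued emf2 over transWT. Both had been low on the transWT array as well. With 1 array per group these differences between backgrounds were not tested.

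Transgenic and non-transgenic arrays differed by at least 2-fold in opposite directions in the wild type and in the mutant for 26 probe sets. Transgene, hygromycin and array go together in both pairs. AT5G62360 was 10.8-fold lower in transWT than in WT and at 1.24 on the log2 scale in rescued emf2 over emf2, and AT5G44440 was at least 7.73-fold lower in transWT and at a log2 ratio of at least 1.34 in rescued emf2 over emf2. AT3G02480, of the late embryogenesis abundant family, was at least 2.70-fold higher in transWT than in WT and at -2.19 in rescued emf2 over emf2. AT2G19970, a PR-1-like gene, was 2.01-fold higher in transWT and at -1.81 in rescued emf2. These differences were not tested either.

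Control RNA probe sets, which the comparisons do not count, were brighter on both transgenic arrays than on the WT array. The medians were 1.21-fold and 1.35-fold for hybridization controls on the transWT and rescued emf2 arrays, and 1.92-fold and 2.48-fold for poly-A controls.

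The transgenic arrays differed from their non-transgenic counterparts in a similar way in both backgrounds, with a correlation of 0.49 across probe sets. A gain difference that depends on signal is argued against, since the correlation was 0.486 after cyclic loess. A different hour of harvest remains a candidate explanation, but COR28 (AT4G33980) cannot single it out. This evening-phased gene, not looked at before, was at a log2 ratio of -1.916 or lower in both comparisons (a bound in transWT over WT). That had been predicted from lower GI, COR27 and AT1G56300, though GI lay within 2-fold in rescued emf2 over emf2 (-0.88). In transWT over WT COR27 has only a bound, at least 1.67-fold lower. Its ratio of -2.67 in rescued emf2 over emf2 starts from an emf2 signal 8.30-fold above WT. COR27 is cold-regulated too, and COR15A and COR15B of the cold list were lower in both comparisons. Harvest hour and a lower cold response were therefore not told apart. Hygromycin and an array batch cannot be told apart from the transgene, because each group lies in 1 level of all of them, and poly-A controls were at least 1.921-fold brighter on both transgenic arrays. An effect of BoEMF2.1 itself stays open.

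Plastid-encoded transcripts were lower in emf2 than in WT, with a median log2 ratio of -1.64 over all 69 genes. An artifact of the emf2 or WT array alone is argued against as the whole cause by the other pair of arrays. There, in rescued emf2 over transWT, the median was -0.6985, below all random lists. Such an artifact could still add to the larger difference between emf2 and WT. Degradation of the whole RNA sample is argued against by the ratio of 5′ to 3′ signal for actin and GAPDH. In emf2 it was no lower than 0.8367 times that in WT. Both are nuclear genes, so degradation of plastid RNA alone was not tested. Compression or scaling of bright signals is argued against by the 0% of 10000 random nuclear lists of like signal with a median as low. A difference in the priming of plastid RNA between samples was not tested. RNA came from whole seedlings. Their share of leaf and root was not measured, so a change in it is not told apart from a change within cells. An effect of the mutation may account for the pattern, as a hypothesis, but variation between plantings stays open.

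The difference between mutant and wild type was smaller with the transgene, with a slope of 0.38 between the separate pairs of arrays. Probe-level measurement error that flattens the slope is argued against as the whole cause, since the slope corrected for it was 0.4246. Variation between plantings of WT and emf2, which adds to the first pair alone, might flatten it too and has no estimate here. Partial replacement of EMF2 by BoEMF2.1 and an effect of hygromycin on both transgenic groups stay open.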

How the results depend on the processing

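The alternatives for the median of plastid-encoded genes and list medians over measured members only were chosen only after seeing the data; the others were set before. The labels give no replicate numbers and each group has 1 array, so no arrays were paired by replicate. The additive fit, which pairs arrays by blocking each effect on the other factor and was also added after seeing the data, called 0 probe sets for background and 7 for the transgene, fewer than the counts of 2-fold ratios, which carry no test. No called value turned its sign under any alternative. Of the alternative values, 57 of 110 counts stayed within 1.5-fold, 10 of 22 kept shares within the exact interval, 13 of 16 correlations within 0.05, 270 of 310 list medians within the SD of random lists' medians, and 1309 of 1320 ratios of single genes on their side of 2-fold. Signal over background sets the limit: 87.6 is the floor below which a ratio is only a bound. MAS5 noise near background was not separated from real differences.

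Counts are given as higher and lower for emf2 over WT, transWT over WT, rescued emf2 over emf2, rescued emf2 over WT and rescued emf2 over transWT, in this order. A 3-fold threshold gave 375 and 574, 167 and 196, 273 and 189, 288 and 374, 72 and 83. A 1.5-fold threshold gave 2446 and 3334, 1599 and 2370, 1938 and 2135, 2042 and 3311, 1213 and 1646. Genes in place of probe sets gave 555 and 842, 270 and 394, 389 and 347, 413 and 739, 165 and 238. With the floor at the 60th percentile they were 672 and 891, 357 and 397, 519 and 394, 562 and 700, 179 and 206. Without a floor they were 2461 and 3674, 2717 and 2104, 2920 and 2045, 2774 and 3217, 1661 and 2337, so the split of transWT over WT leaned the other way. With the floor at the 25th percentile transWT over WT had 895 higher, and rescued emf2 over transWT 519 higher and 780 lower. These settings count fewer or more probe sets by construction.

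The share of emf2 differences kept with the transgene, 19.1% higher and 17.6% lower, was 14.1% and 10.5% at 3-fold, 30.9% and 34.1% at 1.5-fold, 21.7% and 19.8% with the floor at the 25th percentile and 23.6% and 24.2% without a floor. Selected in emf2 over transWT and read in rescued emf2 over WT it was 13.4% and 19.9%, but 10.2% and 12.3% there went at least 2-fold the opposite way, matched probe sets gave 6.38% and 10.1%, and the correlation was 0.10. In the pair the report uses 0.186% and 0.490% went the opposite way. By construction the transgene effect enters this other pair with opposite signs. Read in rescued emf2 over WT it was 37.8% and 53.6%, but both ratios then hold the same WT array. In 100 simulations of unchanged groups against a shared array the shares were 11.8% and 12.6%. The simulations gave every probe set an SD of 0.30 per array, taken from transWT against rescued emf2. That pair has the smallest spread (SD from median deviations 0.43, against 0.65 for WT and emf2). A noisier WT array was not simulated. Independent lists would share 59.2 and 164 probe sets against 407 and 875 observed. The correlation of emf2 over WT with rescued emf2 over WT was 0.67 (simulated 0.50) and the covariance 0.414 (simulated 0.0822), so part of the excess may come from the shared array. The correlation for the mutant effect was 0.59 with the floor at the 25th percentile and 0.32 without a floor, and that for the transgene effect 0.28 without a floor.

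Over measured members only, leaving out those at 0, the list median (log2) of flavonoid genes was 0.68 in transWT over WT and -0.68 in rescued emf2 over transWT, and that of plastid-encoded genes -1.78 in emf2 over WT, 0.88 in rescued emf2 over emf2 and -0.76 in rescued emf2 over transWT. Other list medians moved too, and the cause was not tested. Photosynthesis was 0.12, 0.58 and 0.13 after quantile normalization and 0.22, 0.70 and 0.11 after cyclic loess in transWT over WT, rescued emf2 over emf2 and rescued emf2 over WT. Cold genes were at -1.51, -0.79 and -1.51 in these with the floor at the 60th percentile. Flavonoid genes in transWT over WT were at 0.30 after loess, 1.79 and 0 with floors at the 25th and 60th percentile and 1.77 without a floor, and in rescued emf2 over transWT at -0.30, -1.82, 0 and -1.81. With the floor at the 60th percentile root markers were at -0.018 in transWT over WT and 0.37 in rescued emf2 over transWT. Plastid-encoded genes in emf2 over WT were at -1.79 and -1.20 with floors at the 25th and 60th percentile and -1.78 without. In transWT over WT they were at 0.11 after quantile normalization, 0.14 after loess and 0.30 with median scaling. In rescued emf2 over emf2 they were at 0.65 with median scaling, 0.91 and 0.18 with these floors and 0.90 without. In rescued emf2 over WT they were at -0.49 with median scaling, -0.44 with the floor at the 60th percentile and -0.67 without. In rescued emf2 over transWT they were at -0.80 and -0.56 with these floors and -0.80 without.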

Other observations

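The genes and families here were picked after their values were seen, the families from a scan of 33 by symbol prefix, except the small EXLA and EXPB families and single genes, which were outside it; of the tests, the one on leucine breakdown had its prediction written before the 5 genes were looked at. In the scan, 29 of 165 combinations of family and comparison lay outside the central 95% of random lists matched on signal, where 8.25 would be expected from the percentiles alone; the comparisons share arrays.

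Of 8 measured autophagy genes, ATG3 and 7 members of the ATG8 family, which coats autophagosomes, 2 were at least 2-fold higher in emf2 than in WT, ATG8B by 3.27-fold and ATG8D by 2.98-fold. The other ATG8 genes lay within 2-fold, from 1.44-fold (ATG8E) to 1.99-fold (ATG8G), and ATG3 was at a log2 ratio of -0.01. The family median was 0.98 (percentile 99.96) in emf2 over WT, 0.47 (percentile 99.1) in transWT over WT and 0.25 (percentile 89.7) in rescued emf2 over transWT, which does not use the WT array. RALF-like signalling peptides had a median of 0.95 over 7 genes (percentile 99.8) in emf2 over WT. It was 0.34 (percentile 94.9) in transWT over WT and 0.29 (percentile 90.9) in rescued emf2 over transWT, both inside the central 95%. RALFL27 was 3.03-fold, RALFL22 2.76-fold and RALFL32 2.56-fold higher in emf2, while RALFL34 was 2.06-fold lower. Of 10 genes of the IQD family of calmodulin-binding, microtubule-associated proteins, 4 were at least 2-fold lower in emf2 than in WT, among them iqd21 (at least 5.87-fold) and IQD31 (4.08-fold). The IQD median was -0.96 (percentile 0.09) in emf2 over WT but also -0.69 (percentile 0.17) in transWT over WT, and -0.32 (percentile 3.22) in rescued emf2 over transWT, so the shared WT array takes part in the first 2 values. Of 5 CRR genes, which act on the chloroplast NDH complex through RNA editing or assembly, 3 were lower in emf2 (median -1.31 in emf2 over WT, -0.39 in transWT over WT and -0.69 in rescued emf2 over transWT): CRR41 by 3.50-fold, CRR21 by 3.10-fold and CRR42 by 2.48-fold. The nuclear NDH subunit genes NdhN, NdhS and NdhL, singled out after their values were seen, were 3.42-fold, 3.09-fold and 2.41-fold lower in emf2 than in WT, and at log2 ratios of -1.04, -0.10 and -0.88 in rescued emf2 over transWT.

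Expansin genes went both ways in emf2 over WT. The expansin-like genes EXLA1 and EXLA2 were 3.71-fold and 3.11-fold higher and EXPA20 at least 2.71-fold higher. EXPB3 was 7.65-fold lower and EXPA15 3.34-fold lower, while EXLA3 lay within 2-fold (log2 -0.02). EXLA2 (1.61), EXPB3 (-1.13) and EXPA15 (-1.43) moved the same way in transWT over WT, so the shared WT array takes part. EXLA1 (0.58) lay within 2-fold there, and EXPA20 has only a bound (0.41). The WT signal of EXLA2 (87.9) was just above the floor. Rescued emf2 over transWT, without the WT array, gave 1.58 for EXLA1, 1.07 for EXLA2, -1.69 for EXPB3, 0.51 for EXPA20 and -0.36 for EXPA15. In transWT over WT, 2 of 5 beta-tubulin genes were lower, TUB1 by 2.32-fold and TUB5 by 2.17-fold, with a median of -0.83. In rescued emf2 over emf2, 2 of 5 were lower as well, TUB1 by 2.99-fold and TUB9 by 2.01-fold, with a median of -0.19, and the median in emf2 over WT was -0.49. The medians in emf2 over WT, and for tubulins in transWT over WT, kept their sign under each of the 4 other scalings, between 0.92 and 1.02 for the autophagy genes, 0.95 and 1.05 for RALF-like genes, -0.96 and -0.80 for IQD genes, -1.31 and -1.27 for CRR genes and -0.89 and -0.73 for beta-tubulins. AGL24, a promoter of flowering, had signals of 58.9 in emf2 and 63.6 in rescued emf2 against 1.0 in WT and 1.70 in transWT, all below the floor, so no fold is given.

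A hypothesis was taken from IVD and MCCA, mitochondrial enzyme genes of leucine breakdown. IVD was 4.43-fold higher than WT in emf2, 3.17-fold in transWT and 8.12-fold in rescued emf2, and MCCA 3.67-fold, 4.55-fold and 8.83-fold. All 3 ratios of a gene divide by the same WT array, so a low reading there raises them together. A wider rise of branched-chain amino acid and related mitochondrial breakdown genes was predicted to bring at least 4 of 5 genes not looked at before to at least 1.5-fold above WT on all 3 other arrays. Of these, 2 were: MCCB (1.62-fold, 1.69-fold and 3.12-fold) and ETFQO (1.58-fold, 1.90-fold and 2.98-fold). D2HGDH, the electron transfer flavoprotein subunit gene ETFBETA and the proline dehydrogenase gene AT5G38710 were not, so the wider rise on all 3 arrays is argued against. In emf2 these 3 were 1.21-fold, 1.49-fold and 2.34-fold above WT. In transWT they were 1.01-fold, 1.04-fold and at least 1.08-fold lower. In rescued emf2 D2HGDH was 1.24-fold lower, ETFBETA 1.41-fold higher and AT5G38710 1.15-fold higher.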
